A study of Candida albicans SC5314 with 6 samples.

How the data were processed

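RNA was measured in 6 cultures of the yeast *Candida albicans* strain SC5314, 3 left untreated and 3 exposed to 20 µg/ml fludioxonil. Per the labels, cells were taken from a preculture in YNB with 2 g/L glucose to RPMI-1640 medium at an optical density of 0.1 and grown for 30 min. No solvent is named for the untreated cultures. The labels' protocols give bead disruption and column purification of RNA, and Cy3 labelling from 500 ng of total RNA. Replicate 3 of each group was treated with DNase and the others were not.

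The scanner files hold intensity values that were made with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, per the file headers, on a 1-colour custom array of design 028105. Its processed signal is the spot's intensity after background subtraction and detrending across the array, per the file headers, and was not scaled between arrays. A deposited table of values for the same spots ranked the spots of each array in the same order as the processed signal for 100% of spots. Its columns each had a median of 11.03 and, once sorted, differed by at most 0.00084. The values the authors deposited, used as log2 values here, were thus quantile normalized between arrays. Their log base is not given in the sources used here. Slopes of 0.907 to 1.03 against the log2 processed signal set that scale, and they served as an alternative only. The submitters' processing notes name limma without a version.

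Each array held 15744 spots, of which 15208 carried probes for genes. These were 12442 probes for 6203 gene identifiers, 5940 beginning with CAL and 263 with CAF. On each array 10324 probes were spotted once, 2082 in duplicate and 36 at 20 positions. The files pair probes with these identifiers and give no gene names. None of them was found among the 6263 genes of the reference table (0 matched), so genes are given by identifier. The gene lists and the tests of lists that were planned, and the genes chosen by name in advance (efflux pumps, ergosterol synthesis and osmotic signalling among them), could not be linked to the array and give no result here.

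The log2 processed signal was set relative to each array's 75th percentile over gene spots. Spots that Feature Extraction marked as outliers, 71 to 171 per array, were left out. Spots were averaged per probe and probes per gene. A gene was tested where 1 of its probes was well above background in at least 50% of its spots on all arrays of at least 1 group. That held for 6030 genes, of which 4 lacked a value on an array, leaving 6026. No gene spot was saturated. No gene detected throughout one group was below background on all arrays of the other (0 genes in each direction). Single arrays or probes of a tested gene could still lie near background. Of the tested genes, 5869 had a probe well above background on all 6 arrays. Fold changes of the others may be limited by the floor.

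Fludioxonil was compared with untreated by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 6026 genes and a threshold of 0.05. The number of arrays limits the precision. The series describes its replicates as biologically independent. Genes to be named were fixed before the data were examined, together with 20 of the 26 alternatives. For genes without a name these were up to 2 rises and 2 falls past the threshold and in the same direction in all same-numbered pairs. The procedure was tested on simulated data with the measured means and residual spread, with 200 of 6026 genes changed in 10 simulations. It recovered 11.5% of genes changed 2-fold, 53.9% of those changed 4-fold and 87.4% of those changed 16-fold, with 5.1 false calls on average. The simulated arrays were independent, so these figures leave out any effect of shared day or slide. The adjusted threshold is also looser where more genes change. With only 2 genes called in the data, these rates may overstate the recovery here.

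Replicate numbers pair the cultures, because the labels give same-numbered cultures a shared day of cultivation. Across genes, the deviations of same-numbered arrays from their group means correlated at -0.016, 0.440 and 0.338 for pairs 1, 2 and 3. The arrays lay on 3 slides, called A, B and C here. Slide A held untreated replicate 2 and fludioxonil replicates 1 and 2, slide B untreated replicate 3, and slide C untreated replicate 1 and fludioxonil replicate 3. Both arrays of pair 2 thus lay on slide A and those of pair 3 on slides B and C, while pair 1 was split between slides A and C. The correlations of the pairs therefore cannot tell a shared day from the slides.

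The alternatives fixed in advance were quantile normalization, a common median, the authors' values, other filters on dim probes, the brightest probe of each gene, the replicate number or slide as a block, slide A alone, another variance model, and leaving out arrays or pairs. The 6 others were chosen after seeing the data. They were normexp background correction with an offset of 50 in 2 forms, the median over spots, array weights, slide A against the rest as a block, and the removal of spots in windows of signal loss. Normexp was planned on the mean signal, which the files do not hold, and was run on the median signal. That signal is the one before detrending, so these 2 forms change the input as well as the correction. A window of signal loss was 9 by 9 spots whose deviations from the slide A arrays had a median under -0.5 or a median absolute deviation over 0.8 on the log2 scale. Those bounds were set after the uneven signal of slides B and C had been seen. Spots were removed on each array separately, so a gene's value could rest on different probes on different arrays. Differences in brightness between its probes can then enter the fold change.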

Results

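Transcript levels of *C. albicans* SC5314, the laboratory reference strain of this pathogenic yeast, were measured after 30 min in RPMI-1640 with or without fludioxonil, a phenylpyrrole fungicide known to act through fungal hybrid histidine kinases and osmotic stress signalling. The 6 arrays comprised 3 untreated and 3 fludioxonil-treated cultures. Gene spots well above background made up 99.6%, 99.4% and 99.8% of those on the arrays of slide A (untreated replicate 2, fludioxonil replicates 1 and 2). The share was 91.9% on slide B (untreated replicate 3), and 93.0% and 94.5% on slide C (untreated replicate 1 and fludioxonil replicate 3). The median processed signal of gene spots lay between 1459 and 2696 across arrays.

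The comparison asked which transcripts differed between treated and untreated cells. CAL0003382 rose 22.6-fold, from a log2 level of -2.95 ± 0.11 (SD, n = 3) relative to the array's 75th percentile in untreated cells to 1.55 ± 0.29 (SD, n = 3) with fludioxonil. Its log2 difference was 4.50 ± 0.24 (SE), with an adjusted p of 0.00526 in limma. CAL0001415 rose 5.08-fold, from -4.01 ± 0.07 to -1.66 ± 0.08 (SD, n = 3 each), a log2 difference of 2.35 ± 0.20 (SE) with an adjusted p of 0.0451 in limma. Both were higher in all 3 same-numbered pairs, as the rule for naming genes required. Both of the probes for each gene were higher with fludioxonil, by 4.64 and 4.35 for CAL0003382 and by 1.93 and 2.77 for CAL0001415 on the log2 scale. What these identifiers encode is not given in the sources used here.

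These were the 2 genes of 6026 that passed the threshold in limma, and both changed at least 2-fold. With the replicate number as a block, 0 genes passed it and 745 had an unadjusted p under 0.05. The log2 differences were then 4.50 ± 0.23 (SE) for CAL0003382 (adjusted p of 0.0808 in limma) and 2.35 ± 0.22 (SE) for CAL0001415 (adjusted p of 0.107 in limma). The same differences had SEs of 0.24 and 0.20 without the block. Blocks and left-out arrays leave fewer degrees of freedom for the residual spread. Counts of 0 there need not reflect an effect of day, slide or array. CAL0001415 also missed the threshold with quantile normalization, a common median, the authors' values, no filter on dim probes, the brightest probe or another variance model (adjusted p of 0.0528 to 0.0746 in limma), and its log2 difference ran from 1.73 to 3.02 over the 26 alternatives. The 3.02 came without spots in windows of signal loss and exceeds both of its probes over all spots (1.93 and 2.77). With slide as a fixed block the count was also 0, with 670 genes at an unadjusted p under 0.05. Without untreated replicate 1, fludioxonil replicate 1 or fludioxonil replicate 2 it was 0, without untreated replicate 3 or fludioxonil replicate 3 it was 1, and without untreated replicate 2 it was 29. Untreated replicate 2 is the only untreated array of slide A. Without it the comparison comes close to slide A against slides B and C.

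**Figure D1:**
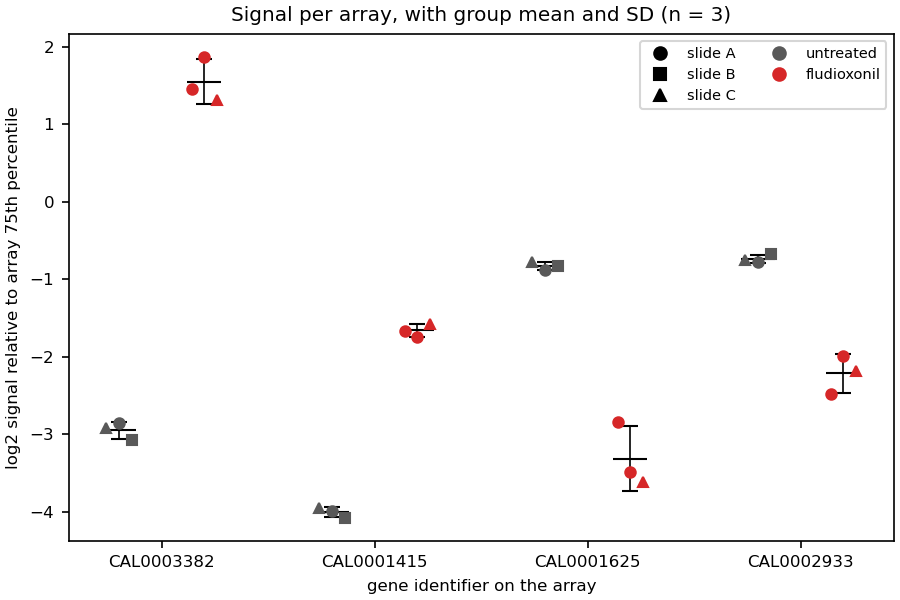
Log2 signal of 4 genes on each array relative to the array's 75th percentile, with horizontal bars for the group mean and whiskers for the SD (n = 3). Symbols mark the slide and colours the group, and the treated arrays of CAL0003382 and CAL0001415 all lie above their untreated arrays, with mean differences of 4.50 and 2.35.

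No gene passed the threshold as lower with fludioxonil (0 genes in limma, with 208 at an unadjusted p under 0.05). The 2 genes with the lowest p among those that were lower were chosen after their values were seen. CAL0001625 had a log2 difference of -2.49 ± 0.27 (SE, adjusted p of 0.0705 in limma), with means of -0.83 ± 0.05 in untreated and -3.32 ± 0.42 in treated cells (SD, n = 3 each). CAL0002933 had a log2 difference of -1.48 ± 0.22 (SE, adjusted p of 0.167 in limma). Each was lower in all 3 same-numbered pairs, which a low p over the same arrays makes likely. The difference of CAL0001625 was -1.12 after normexp background correction with scaling to the 75th percentile and -1.78 with quantile normalization. It passed the threshold as lower without spots in windows of signal loss (-2.85, adjusted p of 0.0251 in limma) and with slide as a random block (-2.51, adjusted p of 0.0231 in limma), within a range of adjusted p of 0.0231 to 0.652 over the 26 alternatives. Without spots in windows of signal loss, the probes behind its value could differ between arrays.

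At an unadjusted p under 0.05, 574 genes differed, 366 higher and 208 lower, where 301.3 would be expected by chance with independent arrays. These arrays share slides and days, so 301.3 need not be the number without a change here. Single arrays moved the count of 574. It was 311 without fludioxonil replicate 2, 342 without fludioxonil replicate 1 and 371 without untreated replicate 1. It was 1234 without untreated replicate 2, which leaves no untreated array on slide A. It was 205 without both arrays of replicate 1, and array weights gave 1423, the ends of its range over the 26 alternatives. The weights were 3.25 and 3.33 on the treated arrays of slide A and 0.40 to 0.90 on the other arrays. The 1423 thus leans on 2 treated arrays of 1 slide. The excess of higher over lower genes depended on the scaling. Quantile normalization gave 277 higher and 312 lower, and a common median gave 311 and 278. The median difference over all genes was 0.09 and the median SE 0.34 on the log2 scale. With normexp correction of the median signal, which was not detrended, the median of all genes was 0.33 with the 75th percentile and -0.11 with quantile normalization. The shift cannot be assigned to the correction alone. With genes ranked by mean level into classes of equal size, 232 of 2008 genes in the lowest class had an unadjusted p under 0.05, against 166 of 2009 in the middle class and 176 of 2009 in the highest. The 12 genes with 62 to 64 spots each had log2 differences between -0.27 and 0.92, and none passed the threshold adjusted over the list alone (0 genes in limma, lowest adjusted p 0.414, 1 at an unadjusted p under 0.05).

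The arrays differed by slide. The SD of a single spot, estimated from the duplicate spots of a probe, was 0.30 to 0.38 on the log2 scale on slide A. It was 1.18, 1.36 and 0.91 on untreated replicates 1 and 3 and fludioxonil replicate 3. In the last 20 of the 82 columns, the median deviation of the signal before detrending from the slide A arrays was -1.30 on untreated replicate 1, -1.57 on untreated replicate 3 and -0.23 on fludioxonil replicate 3. Each slide A array was compared with the other arrays of that slide. Loss shared by them would not show, so their values do not show that slide A is free of such loss. In the first 10 rows the median deviation was -2.88 on fludioxonil replicate 3, and -0.69 and -0.68 on untreated replicates 1 and 3. On slide A it was -0.58 on fludioxonil replicate 2, 0.29 on fludioxonil replicate 1 and 0.38 on untreated replicate 2. Windows of signal loss held 39.5%, 46.9% and 21.4% of gene spots on untreated replicates 1 and 3 and fludioxonil replicate 3, by bounds set after those arrays had been seen. Across genes, which are not independent replicates, the 2 treated arrays of slide A correlated at 0.986 with each other and at 0.973 and 0.976 with the untreated array of that slide, which correlated at 0.933 and 0.921 with the other untreated arrays. Fludioxonil replicate 3 correlated at 0.949 and 0.948 with the treated arrays of slide A, at 0.937 with the untreated array of slide A, at 0.922 with the untreated array of its own slide and at 0.926 with untreated replicate 3. The untreated group held 2 of the 3 arrays on slides B and C.

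**Figure D2:**
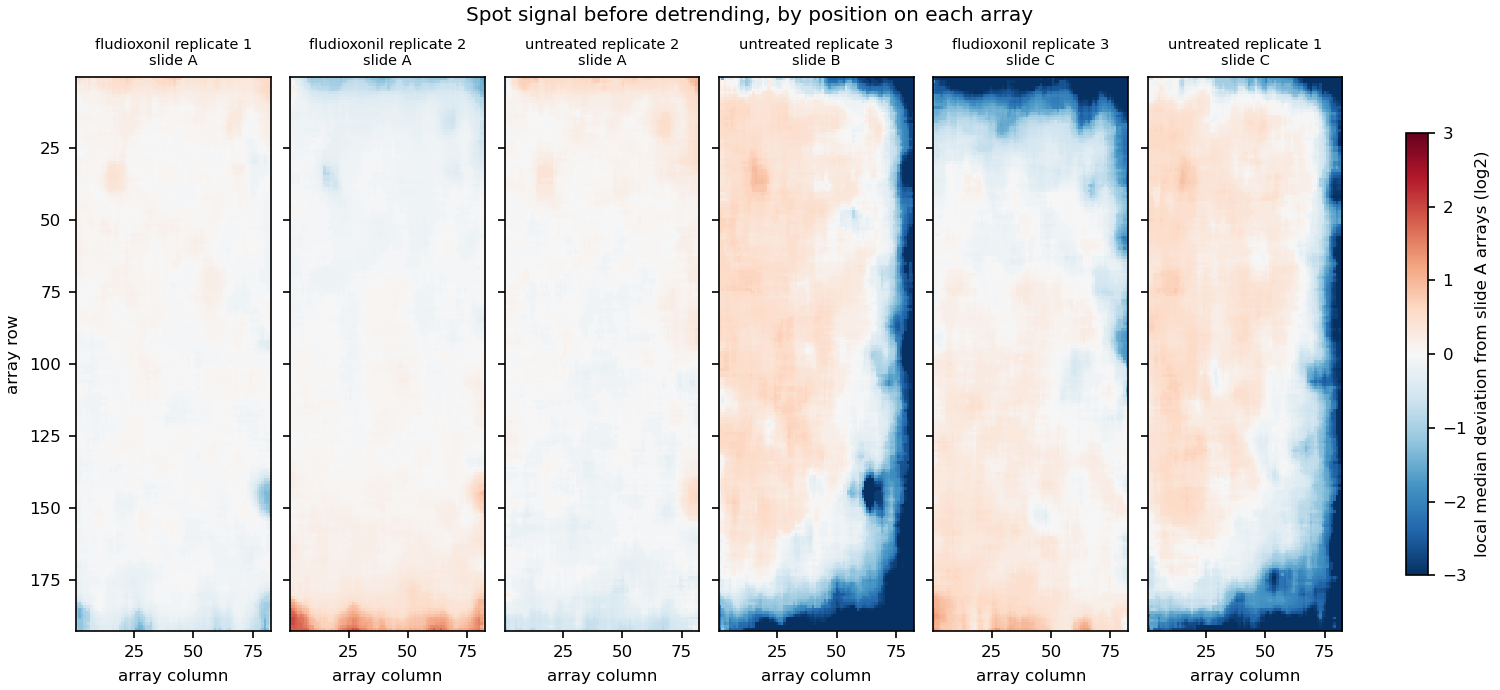
Maps of the 6 arrays by array row and column, coloured by the median, in windows of 9 by 9 spots, of the log2 deviation of each spot's signal before detrending from the mean of the other slide A arrays. The last 20 columns have median deviations of -1.30 and -1.57 on untreated replicates 1 and 3, and the colour scale ends at 3 in either direction.

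Slides A and C each held both groups and share no array. CAL0003382 was higher with fludioxonil by 4.52 on slide A and 4.23 on slide C (log2), and CAL0001415 by 2.29 and 2.37. CAL0001625 differed by -2.29 and -2.84, and CAL0002933 by -1.45 and -1.43. These genes were chosen for a low p over arrays that include those of both slides, so their agreement is not independent support. At least 2-fold differences in the same direction on both slides were found for 125 genes that were higher and 54 that were lower, against 31.6 and 13.9 if the slides were independent. Differences in opposite directions were found for 21 genes, against 41.9. Of the 52 genes at least 4-fold higher on slide A, 47 were also higher on slide C, and of the 16 at least 4-fold lower, 15 were lower on slide C. The differences correlated across genes at r = 0.268 (Spearman's rho 0.174), with 0.120 after normexp correction and the 75th percentile, 0.305 after normexp and quantile normalization, and 0.317 without spots in windows of signal loss. These counts carry no test, because slide C held 1 array per group and slide A 1 untreated array, and on slide C the treated culture had been DNase-treated and grown on another day than the untreated one. With normexp and the 75th percentile, 29 genes were lower on both slides.

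**Figure D3:**
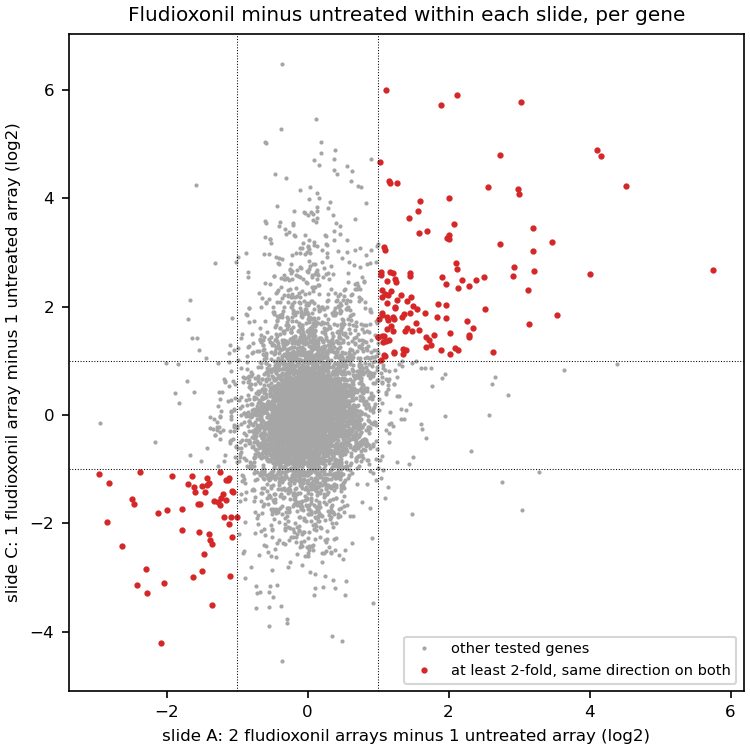
Fludioxonil minus untreated log2 difference of each of 6026 genes on slide A (2 treated arrays, 1 untreated) and slide C (1 array of each group), with dotted lines at 2-fold. Red points mark the 125 genes at least 2-fold higher and the 54 at least 2-fold lower on both slides.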

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

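Normexp correction, removal of spots in windows of signal loss, the median over spots, array weights and slide A against the rest as a block were chosen after the result was seen. Over 26 alternatives the number of genes past the threshold, each also at least 2-fold changed, ran from 0 to 29 beside the 2 reported, with 0 in 9, 1 in 11, 2 in 3 and more in 3 of them. It was 1 with quantile normalization, a common median, the authors' normalized values, no filter on dim probes, the brightest probe of each gene, normexp on the median signal with either scaling, eBayes with trend and robust, or slide A against slides B and C as a fixed block. It was 0 with the replicate block, with slide as a fixed block and within slide A, where 745, 670 and 776 genes had an unadjusted p under 0.05 in limma. Slide A has 1 untreated array, assumed to vary like the 2 treated ones, so its 0 says little about stability. The blocks, and leaving out arrays, also leave fewer degrees of freedom for the residual spread. Counts of 0 in those settings need not reflect an effect of day, slide or array. The count was 12 (10 higher, 2 lower, both reported genes among them) without spots in windows of signal loss, which left 4558 genes to test. After that removal a gene's probes could differ between arrays, so the 12 is not a like-for-like count. The count was 13 (11 higher, 2 lower) with slide as a random block, at a consensus correlation of 0.516. Leaving out 1 array or 1 pair gave 0 to 29 genes: 29 without untreated replicate 2, 1 without untreated replicate 3 or fludioxonil replicate 3, and 0 in the others, among them each pair. Untreated replicate 2 was the only untreated array of slide A. Without it the comparison comes close to slide A against slides B and C, a split that called 31 genes. The cause was not tested. CAL0003382 passed in 17 alternatives, with log2 differences of 3.996 to 4.62 and adjusted p of 0.00171 to 0.476, and CAL0001415 in 6, with 1.73 to 3.02 and 0.0116 to 0.984. CAL0001625 passed in 2 (adjusted p 0.0231 to 0.652) and CAL0002933 in 0 (0.0514 to 0.997), and none of the 4 changed sign. Genes at least 2-fold higher on slides A and C numbered 97 to 180 and those lower 29 to 68, the 29 with normexp on the median signal and the 75th percentile, where 86.1% of both were higher against 69.8% as reported and the differences of the slides correlated at 0.120, the lowest of a range up to 0.317. Normexp on the mean signal was not run, because the files do not hold it, and the planned gene lists could not be linked to the array. Slides B and C had 91.9% to 94.5% of gene spots well above background against 99.4% to 99.8% on slide A.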

Other observations

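The tests of local signal loss, of detrending and of a response shared by both slides were chosen after the result was seen, and so were the bounds for windows of signal loss and the comparison with independent slides. The second test of local loss was written after the first had failed to separate the slides.

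Identifiers beginning with CAF had an unadjusted p under 0.05 for 13 of 251 genes, against 561 of 5775 for those beginning with CAL (Fisher's exact test, two-sided, p = 0.0152, the only such comparison of classes, and genes are not independent). Median levels of the classes were -1.70 and -1.43. Without spots in windows of signal loss, the 10 genes that were higher past the threshold had fold changes of 4.50 to 30.1. These may hold differences in brightness between probes, since a gene's probes could then differ between arrays. For CAL0001415 the log2 difference was 3.02 there, above both of its probes over all spots (1.93 and 2.77). Genes higher on both slides numbered 76 in the lowest class of mean level, 31 in the middle and 18 in the highest, and those lower numbered 28, 18 and 8.

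The count of 2 genes was set against all 10 splits of the 6 arrays into 3 and 3, of which 2 gave at least as many, the real split included. The same 2 of 10 held for genes also changed 2-fold. The highest other count was 31, for slide A against slides B and C, where 1425 genes had an unadjusted p under 0.05, a structure of the arrays by slide that calls 31 genes against 2. The 8 remaining splits called 0 genes in limma, with 65 to 239 at an unadjusted p under 0.05 against 574 for the real split, and among the splits that part all 3 pairs the others called 0 with at most 97. Each of those 8 splits put treated and untreated arrays in the same group. Differences by treatment or slide can then enter the residual spread and lower the counts. Those counts all lay under the 301.3 expected by chance with independent arrays, so they do not measure the number without a change. With 10 splits the share cannot fall under 0.05, which leaves no verdict on chance. With slide as a fixed block 0 genes passed, yet the log2 differences stayed at 4.40 ± 0.24 for CAL0003382 and 2.33 ± 0.19 for CAL0001415 (SE), against 4.50 ± 0.24 and 2.35 ± 0.20, with adjusted p of 0.160 and 0.231 in limma. That block leaves fewer degrees of freedom for the residual spread, and untreated replicate 3, alone on slide B, then adds nothing to the comparison.

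Duplicate spots of 1 probe disagreed on slides B and C, and the SD stayed at 1.22 or more before detrending and at 0.80 or more among the brighter probes, which argues against detrending and against dim probes as the whole cause. Local loss of signal on the slide surface was tested first by the correlation of deviations of adjacent spots, predicted over 0.3 on slides B and C and under 0.2 on slide A. Between adjacent rows it was 0.395, 0.378 and 0.312 on untreated replicates 1 and 3 and fludioxonil replicate 3. On slide A it was 0.340 and 0.252 on fludioxonil replicates 2 and 1 and 0.113 on untreated replicate 2. Between adjacent columns it was 0.225 to 0.280 on slides B and C and 0.078 to 0.295 on slide A, so the prediction was not met. A second test, of duplicate differences against those of their 8 neighbours, was predicted over 0.3 on slides B and C and met that with at least 0.610, but slide A gave 0.466 to 0.663 (before detrending 0.786 to 0.829 against 0.519 to 0.696), so a stricter reading, adopted after these values were seen, takes it as not separating the slides on processed values. Without spots in windows of loss, the duplicate SD fell to 0.53, 0.44 and 0.44 on untreated replicates 1 and 3 and fludioxonil replicate 3. On slide A it was then 0.23 to 0.30. Those windows were chosen by low or scattered signal, so part of the fall follows from the choice. Local loss, seen in the edge columns, may underlie the disagreement, but the tests leave it open, and no biological explanation was tested.

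More genes were higher than lower on both slides, at 69.8%, but each slide's own counts give 69.4% if the slides were independent, so the share says nothing of genes common to both. Genes higher and lower on both slides exceeded the numbers for independent slides alike, 3.96 and 3.88 times. The share was predicted to fall to 50% or less if signal loss on the untreated array of slide C or scaling to the 75th percentile were the cause, and was 68.3% without spots in windows of signal loss and 68.0% with a common median. Independent slides give 65.5% and 61.3% there, within the exact 95% intervals of 59.98% to 75.9% and 60.5% to 74.8%, so that prediction was wrong and neither explanation is decided. These intervals treat genes as independent and do not measure the spread between arrays. A response to fludioxonil shared by both slides was set against the correlation of the differences, 0.268 (0.120 to 0.317 over the alternatives). It was -0.070 for the difference between the 2 treated arrays of slide A with slide C. The correlation carries no information on which direction is commoner and leaves a shared response open too. Day of cultivation, which differs between the arrays of slide C, also stays open. DNase treatment differs there as well. No array of slide A was DNase-treated, so DNase treatment alone cannot give differences shared by both slides.

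On untreated replicate 1 the highest processed signal was 1533800, above the scanner's saturation value of 778070, while the highest median signal before detrending was 196000. Dark corner spots had a log2 processed signal of 8.05 and 7.12 on untreated replicates 1 and 3, against 1.36 to 2.35 on the other arrays. The mean signal of a selected set of spike-ins relative to the 75th percentile was 1.09 to 1.97 on slide A and -0.36 to 0.04 on slides B and C (log2). Spike-ins outside that set were not summarized.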
